A study of Arabidopsis thaliana with 6 samples.

How the data were processed

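Seedlings of 2 genotypes, wild type and OsTOP6A1 transgenic, were each represented by 3 arrays of the Affymetrix Arabidopsis platform. Per the labels' protocols, total RNA was extracted with TRIzol and converted to biotin-labelled cRNA, which was hybridised by the manufacturer's procedure. The deposited values are probe set intensities on a linear scale with 1 decimal. The software and scaling behind the deposited intensities are not given in the sources used here. In the values themselves every array had the same mean intensity of 100.0 after trimming 2% at each end, so the arrays were taken as already scaled and were not normalized further. Detection calls, probe-level intensities and scan batches were not used here, and the number of arrays, not a counting depth, limits the precision.

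Of 22810 probe sets, 64 control probe sets were left out of the tests and 22746 were tested. Probe sets were named through the platform annotation, in which 13513 tested probe sets had 1 gene, 503 had several and 8730 were not listed. Gene names were updated by gene identifier through the RefSeq gene table of assembly TAIR10.1, which held the gene of 13436 probe sets (13286 genes). Probe sets with several genes or none were tested but not named. Among the 144 genes with more than 1 named probe set, 2 had probe sets called in opposite directions. Lists and neighbour tests used 1 probe set per gene, the one with the highest mean over the 6 arrays.

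Intensities were converted to log2(intensity + 16). The genotypes were compared over all 6 arrays, transgenic minus wild type, with lmFit and eBayes of limma 3.58.1 in R 4.3.3, without a variance trend or block, and p-values were adjusted by the Benjamini-Hochberg method over the tested probe sets. The threshold was an adjusted p of 0.05, with a second count at a fold change of at least 2. Gene lists with at least 3 named genes were tested with camera at a preset correlation of 0.01, again with a correlation estimated per list, and with fry. The test, the samples, the alternatives, the rule for named genes and 22 gene lists were fixed before the data were examined. A further 30 lists, the minimum of 3 genes and the thresholds for presence and absence of a signal were chosen after the files or their annotation had been seen. The named genes were the 12 largest rises and 12 largest falls among probe sets past the threshold with 1 gene and no overlap between the genotypes, up to 2 members with the smallest p among those past the threshold in each list without a call of its own, the topoisomerase 6 relatives and partners whatever their values, and the control probe sets for RNA integrity. For the added lists the same rule was applied where at least 3 members passed, and members named outside it were chosen after their values were seen.

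The tests were checked on simulated arrays made from the measured means and spreads of the 22746 probe sets. Of 66 probe sets changed by a log2 fold of 0.5, 40.9% were recovered. Of 67 changed by 1 and 67 changed by 2, 86.6% and 100% were recovered. Among the 155 simulated calls 1.9% were unchanged probe sets. Far fewer probe sets changed in the simulation than were called in the real comparison (3751). Fewer changed probe sets make the adjusted p stricter, so these shares do not carry over to the real comparison. In a simulated list test on 13286 genes, 0% of 30 unshifted lists passed. The simulated noise was independent between genes, so this does not cover lists of correlated genes.

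The alternatives were quantile normalization, centring of array medians, removal of the dimmest probe sets or of those with a cross-hybridisation suffix, other variance models, array weights, pseudocounts of 1 and 64, a block for the replicate number, and omission of each array in turn.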

Results

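Transcript levels were measured in whole light-grown Arabidopsis thaliana seedlings of the Columbia background, 10 days old, on 6 Affymetrix arrays. Wild type seedlings and seedlings of a transgenic genotype that overexpressed a rice cDNA, OsTOP6A1, were represented by 3 arrays each. OsTOP6A1 encodes a subunit A protein of topoisomerase 6, the enzyme that passes one DNA duplex through a break in another. The labels describe the 3 samples of each genotype as biological replicates and do not say how many independent transgenic lines they came from. The array carries Arabidopsis sequences, and no probe set was identified here as reporting the rice transgene, so its level was not analysed here. Array medians lay between 37.5 and 39.3 intensity units, and between 34.9% and 36.0% of all probe sets had an intensity of 16 or less. Pairs of arrays of 1 genotype had Pearson correlations across probe sets of 0.991 to 0.995, and pairs of different genotypes of 0.975 to 0.978. The first principal component held 66.7% of the variance and placed all 3 wild type arrays at negative scores and all 3 transgenic arrays at positive scores. The precision of every value below is limited by the number of arrays.

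The comparison of the genotypes asks which Arabidopsis transcripts differed when the rice topoisomerase subunit was overexpressed. In transgenic seedlings the largest rises among named genes began with ECS1 (AT1G31580), a gene for a cell wall protein, whose mean intensity was 5.2 ± 0.62 (SD, n = 3) in wild type and 1082 ± 110 (SD, n = 3) in transgenic seedlings. AT2G25510 rose from 9.77 ± 5.08 to 1106 ± 357 (SD, n = 3 each). AT1G23960 rose from 0.73 ± 0.23 to 182.0 ± 9.45, and AT5G45500 from 0.8 ± 0.26 to 165 ± 11.7 (SD, n = 3 each). Among the falls, AT5G20700 went from 1382 ± 57.5 to 251 ± 15.5 and AT5G15360 from 99.8 ± 6.32 to 7.27 ± 4.22 (SD, n = 3 each).

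Of 22746 probe sets tested, 3751 passed an adjusted p of 0.05 in limma, 1861 of them higher and 1890 lower in transgenic seedlings. A change of at least 2-fold was also met by 375 probe sets, of which 266 rose and 109 fell. That count depended on the pseudocount, with 515 rises and 259 falls at 1, and 111 rises and 27 falls at 64. The median absolute log2 fold change of the 3751 probe sets was 0.45. In 100% of them the 3 arrays of one genotype all lay above the 3 of the other, which their selection by p on the same arrays nearly forces. Among all probe sets, without selection, this held for 34.9% and would hold for 10% by chance. Without a single array the count of 3751 fell to 2358 (wild type replicate 2), 2323 (wild type replicate 3), 2290 (transgenic replicate 2) and 2181 (transgenic replicate 3). A named gene was given for 13436 of the tested probe sets, and 158 of the 375 probe sets changed at least 2-fold had none, among them some with changes larger than those of named genes.

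**Figure D1:**
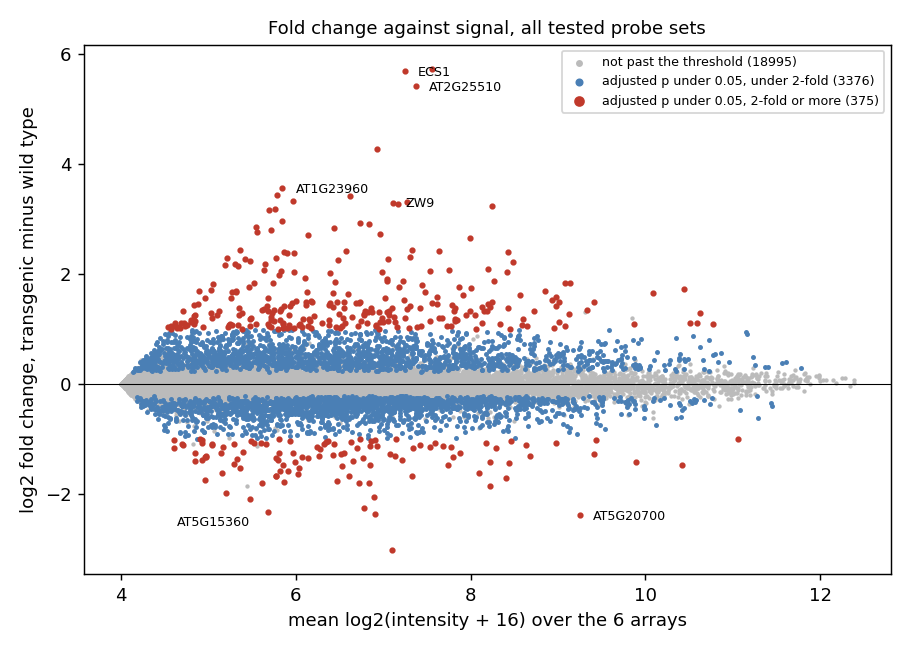
Each point is 1 of the 22746 probe sets tested, with its mean log2(intensity + 16) over the 6 arrays on the x axis and its log2 fold change, transgenic minus wild type, on the y axis. The 375 probe sets past an adjusted p of 0.05 and 2-fold are in red, with 266 above and 109 below the line at 0.

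Further rises of known gene families included AT5G26260, a TRAF-like protein gene, with a log2 fold change of 2.73 (SE 0.12, limma adjusted p = 1.19e-05), and AT2G33220, which encodes a GRIM-19 subunit of mitochondrial complex I, with 2.44 (SE 0.09, limma adjusted p = 8.16e-06). ZW9 (AT1G58270) rose by 3.3 and AT5G44580 by 3.31 on the log2 scale. AT2G14460 rose by 3.17, AT2G43535 by 2.94, AT3G43740 by 2.86 and AT5G20790 by 2.85. These fold changes are on the log2(intensity + 16) scale, which understates changes of dim probe sets such as AT3G43740, with a mean of 1.4 ± 0.8 in wild type and 110.1 ± 1.77 in transgenic seedlings (SD, n = 3 each).

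The 12 largest falls included genes of enzymes and secreted proteins, and whether such genes fell more often than others was not tested. AT1G02300, a cathepsin B-like cysteine protease gene, fell by 2.07 (SE 0.10, limma adjusted p = 2.44e-05) on the log2 scale. AT5G55450, of the lipid transfer protein family, fell by 1.87, with a mean intensity of 565 ± 134 in wild type and 141 ± 9.93 in transgenic seedlings (SD, n = 3 each). AT3G29410, a terpene synthase-like gene, fell by 1.80, AT1G18980, a germin-like gene, by 1.80, AT5G38020, a gene of the carboxyl methyltransferase family, by 1.68, and AT5G35940, a jacalin-type lectin gene, by 1.67. AT3G48640 fell by 1.99, from a mean intensity of 62.5 ± 37.8 to 2.47 ± 0.84 (SD, n = 3 each), with a log2 SE of 0.28, the largest among the 12 falls. AT2G35820 fell by 1.77, AT3G10020 by 1.68 and AT3G16700 by 1.67. Of the 24 genes with the largest rises and falls 1, AT3G48640, lost its call in an alternative setting, which was the test without variance moderation (adjusted p = 0.0593).

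**Figure D2:**
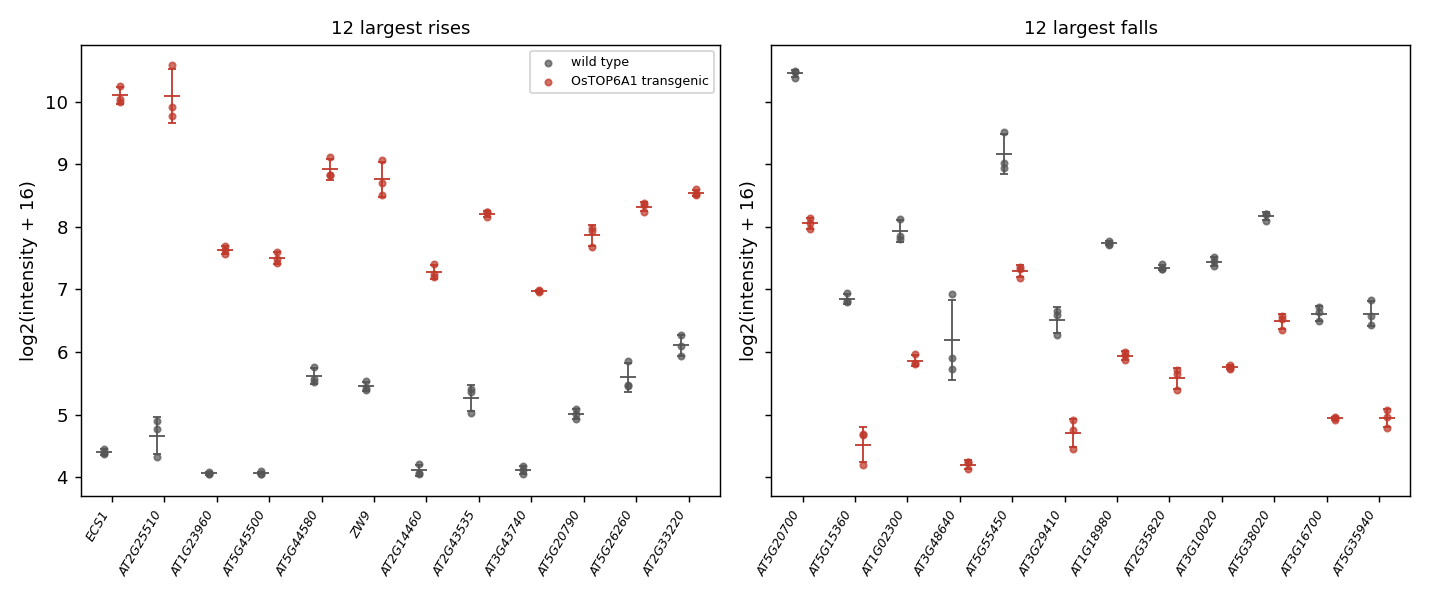
Log2(intensity + 16) of each array for the 12 named genes with the largest rises (left) and the 12 with the largest falls (right); points are arrays, bars are means and whiskers are SD over 3 arrays. For each gene the 3 transgenic arrays (red) lie on one side of the 3 wild type arrays (grey).

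The Arabidopsis genes related to the transgene were mostly dim on the array. SPO11-1 (AT3G13170) and SPO11-2 (AT1G63990) encode relatives of the topoisomerase 6 A subunit that act in meiosis. Their log2 fold changes were -0.33 (limma adjusted p = 0.116) and 0.18 (limma adjusted p = 0.284). With a block for the replicate number SPO11-1 passed (limma adjusted p = 0.0321), at mean intensities of 5.9 in wild type and 1.37 in transgenic seedlings. BIN4, also known as MID (AT5G24630), a component of the plant topoisomerase 6 complex, had means of 16.4 ± 3.12 and 15.3 ± 4.13 in wild type and transgenic seedlings (SD, n = 3 each). Topoisomerase 2 (TOPII, AT3G23890) had means of 118 ± 5.62 and 114 ± 14.5, and TOP3A (AT5G63920) of 26.2 ± 0.6 and 25.1 ± 1.05 (SD, n = 3 each). The list of topoisomerases and their partners had 5 named members, of which 0 passed the threshold, and its camera test gave an adjusted p of 0.794. RHL2, TOP6B and RHL1, the other subunits and partners of the plant enzyme, had no named probe set in the annotation used here and were not analysed here.

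Members of the lists fixed beforehand changed about as often as other genes, with 7 of 47 named members past the threshold (14.9%, beside 15.3% of all named probe sets). In the auxin list GH3.3 (AT2G23170), an auxin-conjugating enzyme gene, fell by 0.64 on the log2 scale, while 3 of the 5 named members did not pass. IAA29 (AT4G32280), an auxin-inducible repressor gene, fell by 0.40, but its intensity was under 16 on every array. Its means were 11.9 ± 2.5 in wild type and 5.17 ± 1.4 in transgenic seedlings (SD, n = 3 each). UF3GT (AT5G54060), which glycosylates anthocyanins, rose by 0.63, and the other flavonoid genes with a name, DFR and AT4G14090, had log2 fold changes of 0.36 and 0.40 that did not pass over all probe sets. STZ (AT1G27730), a stress-induced zinc finger gene, rose by 0.39. GI (AT1G22770), a gene of the circadian clock, fell by 0.42 (SE 0.07, limma adjusted p = 0.00874), ARR15 (AT1G74890), a cytokinin-induced response regulator gene, by 0.37, and BHLH101 (AT5G04150), an iron deficiency gene, by 0.34. In the fixed list of abscisic acid, dehydration and cold genes none of the 4 named members passed, although without single arrays up to 2 were called lower, and COR15A, COR47 and LTI30 had log2 fold changes of 0.37, -0.40 and -0.24. Nor did the named photosynthesis genes LHCB4.1, RCA and PSAE-1, with log2 fold changes of 0.12, 0.11 and 0.07, or the root markers EXPA7, EXPA18, PYK10 and NAI2, with log2 fold changes between 0.04 and 0.06.

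Over the 22 lists, 47 of 355 genes had a named probe set, and 2 of these rose and 5 fell. Adjusted over the list alone, 2 members passed in the auxin list, 2 in the flavonoid list and 1 in the touch and rapid stress list. Of the 9 lists with at least 3 named genes, 0 passed an adjusted p of 0.05 in camera, and 2 had an unadjusted p under 0.05. These were the flavonoid list (p = 0.0184, adjusted p = 0.152, p = 0.16 with an estimated correlation) and the touch and rapid stress list (p = 0.0339, adjusted p = 0.152, p = 0.11 with an estimated correlation), both toward higher values in transgenic seedlings. The directional fry test passed 0 of the 9 lists, and its test for change in either direction passed 1, the auxin list (adjusted p = 0.0181), which camera did not pass (adjusted p = 0.485, and adjusted p = 0.842 with an estimated correlation). The flavonoid list passed in camera without transgenic replicate 1 (adjusted p = 0.0219) and with a block for the replicate number (adjusted p = 0.0447). Of the 7 members that changed, GI kept its call without any array, GH3.3 lost it without 2 arrays (transgenic replicates 2 and 3), and IAA29 lost it without each of these and without wild type replicates 1 and 2 (highest adjusted p 0.0895 and 0.0799). The others kept their calls only without 1 array, which was transgenic replicate 1 for UF3GT, wild type replicate 1 for STZ and ARR15, and transgenic replicate 3 for BHLH101, with adjusted p of up to 0.11, 0.0872, 0.141 and 0.101 without the rest.

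Because few genes of these lists had a name, 30 further lists were built from the gene symbols of the annotation before any fold change was computed. Their counts of changed members stand beside the 15.3% of all named probe sets that passed. Whether a count differed from that share was not tested. Among 47 UDP-glycosyltransferases, which attach sugars to small molecules, 10 rose, 5 fell and 32 did not pass. UGT74B1 (AT1G24100), an enzyme of glucosinolate synthesis, rose from 128 ± 20.8 to 596 ± 88.8 and UGT88A1 (AT3G16520) from 161 ± 11.8 to 472 ± 19.4 (SD, n = 3 each), while UGT84A1 fell by 1.15 on the log2 scale. Among 28 expansins and xyloglucan endotransglucosylases, which loosen and rebuild the cell wall, 6 rose and 3 fell. EXGT-A3 (AT2G01850) rose from 360.0 ± 27.4 to 767 ± 14.9, and XTH21 (AT2G18800) had means of 0.33 ± 0.15 and 17.43 ± 3.29 (SD, n = 3 each). Of 22 TBL genes, listed here under wall acetylation, 3 rose and 1 fell, with log2 fold changes of 0.95 for TBL37 and 0.48 for TBL32. The fall among the TBL genes, TBL38, had a log2 fold change of -0.24 and lost its call without each array taken singly (adjusted p of up to 0.132). TBL37 lost its call in the test without variance moderation (adjusted p = 0.0562). Without single arrays the UDP-glycosyltransferases had 6 to 9 rises and 4 falls, and the expansins and xyloglucan endotransglucosylases 4 to 6 rises and 2 to 4 falls.

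The added list with the smallest camera p, called the autophagy list here, held ATG8 genes and ATG3. No other autophagy genes were in the list. Of its 10 named members 5 fell and 0 rose: ATG8D (AT2G05630) by 0.70, APG8A (AT4G21980) by 0.56, ATG8G (AT3G60640) by 0.35, APG8H (AT3G15580) by 0.31 and ATG8H (AT3G06420) by 0.30 on the log2 scale. The ATG8 proteins are ubiquitin-like proteins that are attached to the membranes of autophagosomes. ATG8C had a log2 fold change of 0.40 that did not pass (adjusted p = 0.0534), and 1 member of the list was called higher under quantile normalization and under median centring. ATG3 did not pass either, with a log2 fold change of -0.07 (limma adjusted p = 0.516). The list had a camera p of 0.00427, an adjusted p of 0.128 over the 30 lists and a p of 0.111 with an estimated correlation. ATG8D and APG8A kept their calls without any single array, whereas the calls of ATG8G, ATG8H and APG8H ended without 2, 3 and 5 of the arrays taken singly, with adjusted p of up to 0.0573, 0.0596 and 0.0946.

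Genes of DNA repair and recombination had 4 falls and 0 rises among 22 members, with REV7 (AT1G16590), a subunit of a translesion DNA polymerase, falling by 0.76 and DRT100 (AT3G12610) by 0.54 on the log2 scale. RAD5 and ATRX fell by 0.35 and 0.24, calls that ended without 3 and 5 of the arrays taken singly (adjusted p of up to 0.0712 and 0.128), and the list had a camera p of 0.0733 (adjusted p = 0.319). Among 16 genes of tetrapyrrole synthesis and light harvesting, LHCB4.2 (AT3G08940), a minor antenna protein of photosystem II, rose from 598 ± 61.4 to 1913 ± 99.5 (SD, n = 3 each). CHLM (AT4G25080), of chlorophyll synthesis, rose by 0.42, and LHCB4.3 fell by 0.78, a call that ended without 4 of the arrays taken singly (adjusted p of up to 0.106). Among 17 genes listed by a SWEET or monosaccharide transporter symbol 2 rose and 1 fell, and members under other symbols were not counted. SWEET17 (AT4G15920) and SWEET2 (AT3G14770), sugar transporters of the vacuole, rose by 0.73 and 0.61, and SWEET10 fell by 0.88 (limma adjusted p = 0.00211). In a wider list of 15 cold and dehydration genes 3 rose and 1 fell. DI21 (AT4G15910), named for its induction by drought, rose by 1.91 and SAG29 (AT5G13170), a senescence-associated gene, by 1.11, while COR27 fell by 0.75, a call that ended without 4 of the arrays taken singly (adjusted p of up to 0.0797). In a wider list of 12 jasmonate genes 3 rose and 0 fell (1 to 3 rises without single arrays), while in the fixed jasmonate list 0 of 4 named members passed. Of the wider list JRG21 (AT3G55970) and THI2.2 (AT5G36910) rose by 0.77 and 0.98, calls that ended with a pseudocount of 1 (adjusted p of 0.0559 and 0.0596) and without variance moderation. THI2.2 also had an adjusted p of 0.0538 without wild type replicate 2, and CHLM of 0.0528 without transgenic replicate 3.

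Members of other families also changed. Among 29 genes of secretion and vesicle sorting 2 rose and 5 fell, or 2 and between 2 and 5 without single arrays. The vesicle sorting gene VPS2.2 (AT5G44560) rose by 1.24 and PRA1.F1 (AT1G17700) fell by 0.43 on the log2 scale. BGLU42 (AT5G36890) rose by 0.66 and BGLU15 (AT2G44450) fell by 0.74 among 20 beta-glucosidases, of which 3 rose and 3 fell. Without single arrays 1 to 3 of them rose and 1 to 3 fell. BGLU40, BGLU46 and BGLU27 lost their calls without 4, 4 and 5 arrays taken singly, and BGLU42 in the test without variance moderation (adjusted p = 0.069). ATGSTF13 (AT3G62760) rose by 0.74 and GSTU27 (AT3G43800) fell by 0.46 among 14 glutathione transferases. UBC37 (AT3G24515) rose by 0.90, scpl48 (AT3G45010) rose by 0.49 and scpl31 (AT1G11080) fell by 0.64. The signal peptide genes RALFL32 and CLE41, the only 2 of 16 in their list to pass and chosen here after their values were seen, rose from 39.9 ± 6.4 to 142 ± 12.9 and from 49.7 ± 2.87 to 138 ± 16.7 (SD, n = 3 each). None of the 30 added lists (0) passed in camera, while 2 had an unadjusted p under 0.05, the autophagy list and the RNA polymerase subunits, which lay toward lower values (camera adjusted p = 0.166). The directional fry test passed 4 of these lists, those of MADS-box genes, RALFL and CLE peptides, autophagy, and cold and dehydration, with adjusted p of 0.0119, 0.0139, 0.0253 and 0.0299. With an estimated correlation in camera their adjusted p lay between 0.837 and 0.921, and the MADS-box list had 1 changed member of 40, AGL87. The fry test for change in either direction passed 30, and the list median and mean differed in sign for 8.

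Transcripts encoded in the chloroplast genome changed in both directions. Of 69 chloroplast-encoded probe sets, 12 fell and 5 rose in transgenic seedlings. These were 24.6% of the 69, beside 16.5% of all tested probe sets, and whether the shares differ was not tested. The falls included rpoC2, a subunit of the plastid RNA polymerase, from 349 ± 21.5 to 137 ± 11.7, rps4, a ribosomal protein, from 3005 ± 186 to 1489 ± 104, and psbA, the D1 protein of photosystem II, from 718 ± 91.0 to 333 ± 35.5 (SD, n = 3 each). The rises included ndhA and ndhI, subunits of the NDH complex, by 1.33 and 1.11 on the log2 scale. The other 8 of 10 chloroplast-encoded NDH genes did not pass, and the median log2 fold change of the 10 was -0.03. The genes rpoC2, rps4, psbA, ndhA and ndhI kept their calls without any single array. The count of 17 fell to 8 without wild type replicate 2, transgenic replicate 2 or transgenic replicate 3, and to 5 without variance moderation. The fall of psbC, with a log2 fold change of -1.32, ended without 5 of the arrays taken singly (adjusted p of up to 0.108), and its wild type replicate 1 had an intensity of 345 beside 923 and 787.

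**Figure D3:**
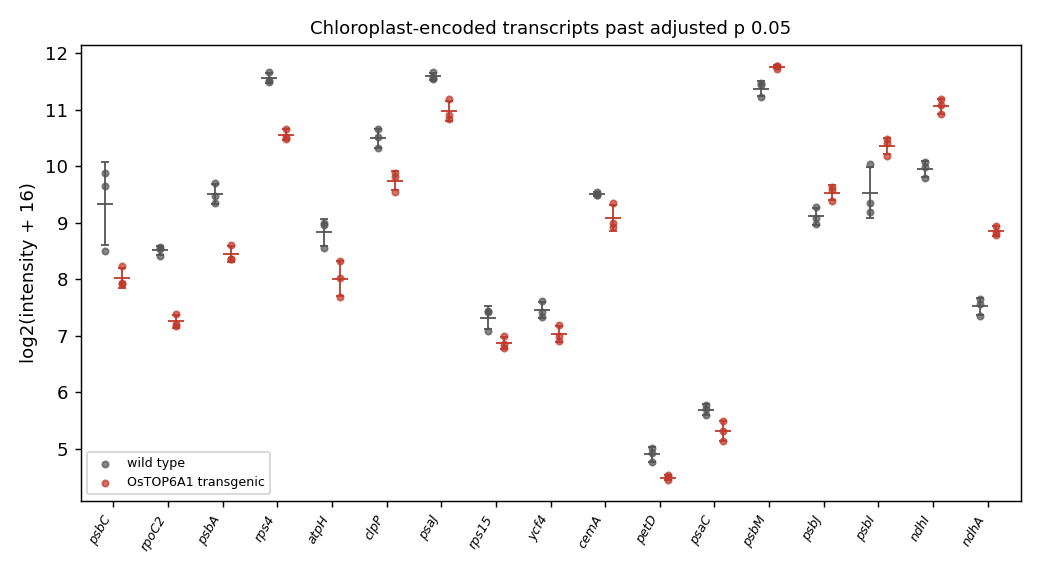
Log2(intensity + 16) of each array for the 17 chloroplast-encoded transcripts past an adjusted p of 0.05, ordered by log2 fold change; points are arrays, bars are means and whiskers are SD over 3 arrays. Of these, 12 are lower and 5 higher in transgenic (red) than in wild type (grey) seedlings.

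Control probe sets gave a reading of RNA integrity. The log2 ratio of the 3' to the 5' actin probe set was 1.14 ± 0.07 in wild type and 1.33 ± 0.01 in transgenic seedlings (SD, n = 3 each), with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 arrays allow. The same ratio for GAPDH was 0.03 ± 0.14 and -0.03 ± 0.05 (exact permutation p = 0.8), and for ubiquitin 0.44 ± 0.04 and 0.37 ± 0.08 (exact permutation p = 0.3; SD, n = 3 each). The actin ratio was higher in all 3 transgenic arrays than in all 3 wild type arrays.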

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

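One of the 64 control probe sets, which no comparison above used, carried a signal in transgenic seedlings well above that in wild type. The control probe set AFFX-r2-At-U12639_at had a mean intensity of 26.7 ± 2.8 in transgenic and 1.2 ± 0.96 in wild type seedlings (SD, n = 3 each), higher in all 3 transgenic arrays, with a log2 fold change of 1.31 (SE 0.08, limma adjusted p = 6.05e-05 when the controls were tested with all other probe sets). The sequence behind this probe set is not given in the sources used here.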

How the results depend on the processing

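Among the alternatives fixed before the data were examined, the count of 3751 probe sets mostly stayed within 1.5 times. It became 2143 with a pseudocount of 1 and 1930 without variance moderation. Without wild type replicate 1 it was 3433 and without transgenic replicate 1 it was 2788, both within 1.5 times. These arrays had the lowest array weights (0.583 and 0.655). Without any of the other arrays it lay between 2181 and 2358. Fewer arrays leave fewer degrees of freedom, but equally so for each array, and the cause of these differences was not tested. The count of 375 at 2-fold or more became 774 with a pseudocount of 1 and 138 with a pseudocount of 64, since the pseudocount sets how far dim probe sets can change, and ranged from 364 to 406 without single arrays. Of the 3751 calls, 3478 were kept under quantile normalization, 2091 with a pseudocount of 1, 1796 without variance moderation and 2113 without transgenic replicate 3. The 9 lists gave 0 calls in camera except 1, the flavonoid list, without transgenic replicate 1 and with the replicate block (range 0 to 1), and fry gave 0 directional calls and 1 for either direction. The 30 added lists, chosen after the annotation was seen, gave 0 calls in camera under every setting run, with 4 directional and 30 either-direction calls in fry, which does not compare a list with other genes. Of the 73 named genes, 3 values changed sign, none of them called: BIN4 became 0.025 without wild type replicate 2 and 0.027 without transgenic replicate 1, and TOPII 0.0072 without transgenic replicate 3 (lowest -0.16 and -0.14, both without transgenic replicate 2). Of 68 called named genes, 15 lost their call in at least 1 setting, 14 of them without variance moderation, a setting added for single genes after the results were seen. With a replicate block the counts were 3592 and 379, and SPO11-1 passed (adjusted p = 0.0321; 0.116 without the block). The numbers were not taken as pairs, as fixed beforehand, since the labels do not say that equal numbers share a batch or day. Same-numbered arrays shared deviations with correlations of 0.191, 0.057 and 0.113. Transgenic replicate 2 correlated better with wild type replicate 3 (0.082) than with its own number. For replicates 1 and 3 no correlation with another number exceeded -0.08 and 0.082, so pairing was not settled by these values. The list tests have no robust option and were not run with it. Signal over background limits the dim probe sets, since about 35% of each array lay at 16 or less.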

Other observations

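The tests of chloroplast transcripts, of presence and absence, of stretches of genes and neighbours, and of other splits of the arrays were chosen after the results they bear on had been seen.

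Cytochrome P450 genes of the CYP71B family in one region of chromosome 3 included rises and falls. CYP71B34 (AT3G26300) rose by 2.43 and CYP71B26 by 0.65 on the log2 scale, while CYP71B23 (AT3G26210), CYP71B24 and CYP71B37 had log2 fold changes of -1.18, -0.65 and -0.42. CYP71B16, CYP71B21, CYP71B22, CYP71B25, CYP71B35 and CYP71B36 of the same region did not pass, with log2 fold changes between -0.35 and 0.33. The call of CYP71B37 ended without 3 of the arrays taken singly. The MADS-box gene AGL87 rose by 2.41, and AT4G16870 and AT1G20390, both annotated as pseudogenes, rose by 2.30 and 1.68. Among 989 annotated pseudogenes as a group 17 rose and 11 fell (13 to 20 and 7 to 14 without single arrays), with a median log2 fold change of 0.01 (camera adjusted p = 0.403).

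Chloroplast-encoded transcripts fell at 12 probe sets and rose at 5. A different share of chloroplast RNA in the samples may shift such transcripts, and alone it would move them to 1 side. The 5 rises beside 12 falls argue only against such a shift as the sole source. A different share together with changes of single transcripts could give both directions and stays open. One deviating array as the sole source is argued against, since at least 2 still rose and at least 5 still fell without each array in turn. An effect of the transgene on the plastid was not tested and stays open.

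A set of probe sets behaved as present in one genotype and absent in the other. The rule asked for an intensity of at most 16 on every array of one genotype and at least 50 on every array of the other. By it 33 probe sets were detected in transgenic seedlings alone and 4 in wild type alone. In any other split of the 6 arrays 0 met the rule. Those splits mix the genotypes on each side, so probe sets that differ by genotype could not meet it there. With limits of 8 and 100 the numbers were 7 and 0, with 32 and 64 they were 55 and 14, and without single arrays the total lay between 37 and 44. The 17 named genes detected in transgenic seedlings alone included ECS1, whose expression is known to differ between Arabidopsis accessions, AT2G25510, AT1G23960, AT5G45500, AT2G14460 and AT3G43740, and the 3 detected in wild type alone were AT5G15360, AT3G29410 and AT3G16700.

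A single insertion site acting on neighbouring genes is argued against, since at most 15% of the 20 named genes lay within any stretch of 50 measured genes, and all 5 nuclear chromosomes held at least 1. A difference in accession or line beside the transgene may also give such a pattern, although the labels give Columbia for all 6 arrays. Neighbours were counted among the 13217 placed genes with a named probe set, so other genes can lie between them. The 211 placed genes changed at least 2-fold formed 8 neighbouring pairs, against a mean of 3.32 in 10000 random placements (one-sided permutation p = 0.0209). The 1809 changed less formed 277 against 247 (same permutation test, p = 0.0182), and whether these excesses differ was not tested. Neighbours that share sequence or regulation would form such pairs as well, and line and genotype coincide in this design, so a difference in line and an effect of OsTOP6A1 on silent genes cannot be told apart here.

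With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. For the count of probe sets past the threshold 1 split, the real one, gave as many (3751, highest other 0), and for those changed at least 2-fold again 1 (375, highest other 0). The other splits mix the genotypes on each side, so their 0 was nearly set in advance and does not measure chance. For the 9 lists and for the 30 added lists all 10 splits gave at least as many as the real 0, which any split must, so this decides nothing. The highest other split gave 2 in each case.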
